A study of Mus musculus with 2 samples.

How the data were processed

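Total RNA of 7 mice per genotype was pooled per the labels, labelled with Cy3 and hybridised to 1 one-colour Agilent mouse array per genotype. The deposited intensity values were extracted with Agilent Feature Extraction 10.10.1.1, per the file headers and the submitters' processing notes, and the array design refers to genome build mm9. Per the file headers the processed intensity was background-subtracted and spatially detrended within each array and not scaled between arrays. Both arrays lay on 1 slide and were read in 1 scan, so neither slide nor scan separates the genotypes. The authors' deposited value table holds the same processed intensity multiplied by 1 constant per array, 2.05 for Il18+/+ and 1.92 for Il18-/-, on a linear scale with no centring. Its column medians were 151.5 and 139.5. What the constants were set to stays unknown, and the table was used as an alternative only.

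Each array held 62976 spots, of which 3671 control spots were left out. The 59305 others carried 55681 probes. Spots flagged as outliers were left out, 124 on the Il18+/+ array and 177 on the Il18-/- array, and no remaining spot was saturated. The processed intensity was set to log2 and the 75th percentile of each array's spots was subtracted, which was an intensity of 694.8 for Il18+/+ and 709.9 for Il18-/-. Spots of 1 probe were averaged. The files used here give an accession and no gene name, so probes were named by matching accessions without versions to RefSeq genes of GRCm38.p6, which named 27235 probes with 1 symbol, none with several, and left 28446 unnamed. No coordinates of that assembly were used except to place genes in order and near each other. A gene was measured when at least 1 probe was well above background on both arrays, and its difference was the mean over such probes, 35632 of all probes being measured. At 1.5-fold or more, 264 genes were higher and 405 lower in Il18-/-, and 68 of these had several measured probes. Of the 68, 64 had all probes on the same side, though they were picked by the mean of the same probes. The other genes at 1.5-fold rest on 1 measured probe each.

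No test was made, since each genotype had 1 pool. Genes were counted at 2-fold and 1.5-fold. The named genes followed a rule fixed before the data were examined, namely Il18, the 12 highest and 12 lowest genes above the lower quartile of level with all probes on 1 side and a name that is not an accession, a clone or a predicted gene, up to 4 members with the largest difference from each list, and up to 5 genes per direction that were above background on 1 array only. Of 33 lists fixed at the same time, 32 had at least 5 measured members and were described by the percentile of their median among 10000 random lists matched on level in 20 bins. A list stood apart at a percentile of at most 2.5 or at least 97.5. A further 6 lists for other organs were chosen after the data were examined, as was the search for clustered spots, namely those at 1.5-fold or more with at least 2 of the 18 nearest spots at 2-fold or more in the same direction.

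The calculations were tested on simulated data for this comparison, with 15737 genes and 200 changed genes and the noise of repeated spots. All 3-fold genes were called at 2-fold and all 2-fold genes at 1.5-fold (100% each), and 0 unchanged genes were called. A list shifted by 0.5 gave a median of 0.51, and 1.5% of 200 unchanged lists stood apart. This noise was the median spread of repeated spots, 0.07, for every probe, with independent list members. It leaves out differences between animals and pools. The simulation therefore checks the calculations and not how many false calls the real arrays would give. Alternatives fixed before the data were examined were quantile, median and loess normalization, no filter and a stricter filter on dim probes, the brightest probe, and the authors' deposited values. Scaling to the spike-in controls was added afterwards. The mean signal was not used here, and the median signal stood in for it with normexp (offset 50) and without background correction. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.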

Results

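Messenger RNA levels were measured in brain tissue of male mice that lacked interleukin-18, a cytokine of the interleukin-1 family, and of wild-type mice at 12 weeks of age. RNA of 7 mice per genotype was pooled, and each pool was hybridised to 1 array, so Il18+/+ and Il18-/- each had 1 sample. The labels name the tissue as hippocampus, while the extraction protocol and part of the design text speak of prefrontal cortex. On the Il18+/+ array 67.2% of the probes were well above background, and on the Il18-/- array 65.4%. Both arrays together measured 15737 named genes. Levels are log2 signals relative to the 75th percentile of each array, and differences are Il18-/- minus Il18+/+. With 1 pool per genotype no difference has a replicate check, no test was possible, and the number of arrays limits the precision. Every value below describes these 2 arrays.

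The probe for Il18, the targeted gene, read 1.37 in Il18+/+ and -0.12 in Il18-/-, a log2 difference of -1.49 or 2.80-fold lower. It was still well above background in Il18-/-. The place of this probe relative to the deleted part of the gene is not known here, so the remaining signal does not check the genotype. Among the 18 measured genes of interleukin-18 and interleukin-1 signalling, 13 were lower and 5 were higher, with a median of -0.05 at the 39.2 percentile of 10000 random lists matched on level. Il1rap, a co-receptor of the interleukin-1 family, was 1.53-fold lower in Il18-/-, and Casp1, the protease that matures interleukin-18, was 1.28-fold lower.

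Which genes differed between the brains of the 2 genotypes was the main comparison. Genes of the choroid plexus, the tissue that secretes cerebrospinal fluid, were lower in Il18-/-, and genes typical of liver and of the medial habenula were higher. The water channel gene Aqp1 was 2.91-fold lower, the coagulation factor gene F5 was 2.93-fold lower and the potassium channel gene Kcnj13 was 2.63-fold lower. Mup20, a major urinary protein gene, was 12.3-fold higher, Ahsg, which encodes the plasma protein fetuin-A, was 8.67-fold higher, and Tac2, which encodes neurokinin B, was 6.98-fold higher. Of the 15737 measured genes, 101 were at least 2-fold higher in Il18-/- and 71 were at least 2-fold lower. At a size of 1.5-fold, 264 were higher and 405 were lower, together 4.25% of the measured genes. These counts were 113 and 107 with normexp background correction, 321 and 300 with loess normalization, and 124 and 1906 when the arrays were scaled to spike-in controls, which lowers every difference by 0.32 and turns each list median between 0 and that size negative. The median difference was 0.01, and 90% of the genes lay between -0.45 and 0.33. Repeated spots of a probe had a median standard deviation of 0.07 for the difference, which covers technical error within these arrays only. Over the 304 measured probes with 10 spots, the 95th percentile of this spread was 0.27. Different probes of 1 gene had a median standard deviation of 0.12.

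**Figure D1:**
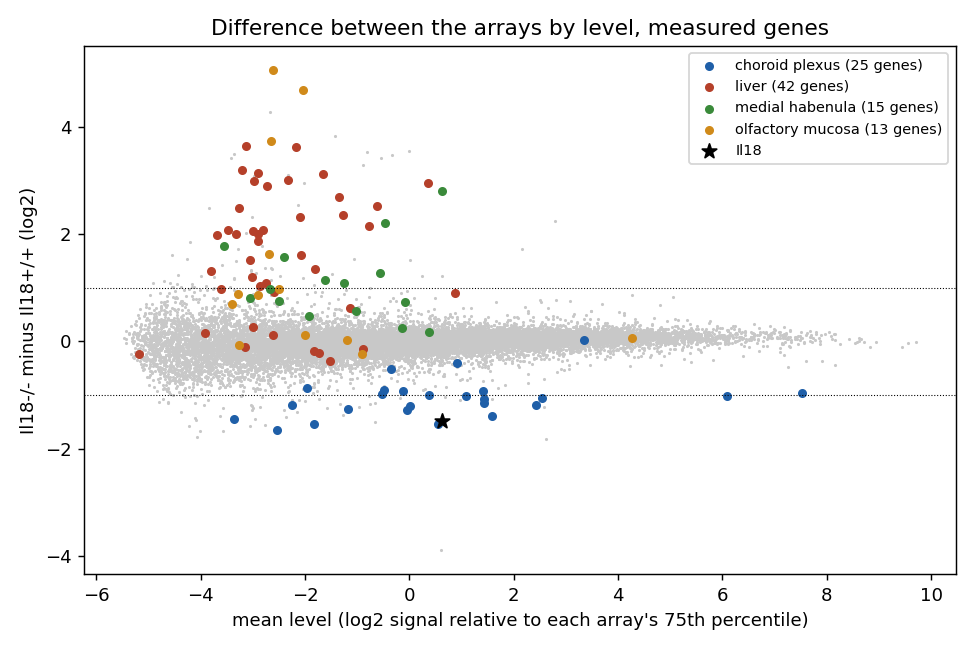
Difference between the arrays (Il18-/- minus Il18+/+, log2) against mean level (log2 signal relative to the 75th percentile of each array), 1 point per measured gene, with dotted lines at 2-fold. Of 25 choroid plexus genes 24 lie below 0, with a median of -1.06, liver genes lie mostly above with a median of 1.93, and Il18 lies at -1.49.

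Among genes above the lower quartile of level whose name is not an accession, a clone or a predicted gene, the 12 highest were Bpifb4, Syt12, Mup20, Mup19, Mup18, Mup17, Mup4, Ahsg, Cad, Serpina1c, Tac2 and Serpina1a. Bpifb4 was 25.7-fold higher and Serpina1c, an alpha-1-antitrypsin gene, was 7.72-fold higher. The Mup and Serpina1 genes are families of near-identical copies, so which member each probe read is uncertain. Syt12, at 14.2-fold, and Cad, at 7.77-fold, were each read by a probe whose neighbouring spots on the glass also read higher in Il18-/-. The 12 lowest were Tmem25, F5, Aqp1, Tex22, Il18, Kcnj13, Trpv4, Klk6, Steap1, Wfdc2, Prr32 and Cryab. AB124611, left out for its accession-like name, was lower than all of these, with a difference of -3.89. Tmem25 was 3.52-fold lower, Tex22 was 2.84-fold lower and the ion channel gene Trpv4 was 2.59-fold lower. Klk6, a serine protease gene, differed by -1.32 on the log2 scale and Prr32 was 2.35-fold lower.

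All 25 choroid plexus genes were measured, and 24 of them were lower in Il18-/-. Of these, 22 were at least 1.5-fold lower and 16 at least 2-fold lower. The median difference was -1.06, below every one of the random lists. Cldn2, a tight junction gene, was 3.13-fold lower, and Col8a1, a collagen gene, was 2.74-fold lower. Ttr, which encodes the thyroxine carrier transthyretin, went from 8.01 to 7.05, and Enpp2, which encodes autotaxin, went from 6.59 to 5.57. Slc29a4 was the 1 member that was not lower, with a difference of 0.03. The mural and meningeal list had a median of -0.16 at the 0.02 percentile, with Igf2 2.94-fold lower, Igfbp2 2.10-fold lower, Mgp 1.76-fold lower and Slc13a4 1.71-fold lower. Igfbp2 also stands in the choroid plexus list. Ependymal genes had a median of 0.00 at the 52.4 percentile, with Tmem212 1.76-fold higher and Spef2 1.36-fold lower.

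Myelin genes were lower as a group, by less. Of 20 measured members 18 were lower, with a median of -0.29 below every random list, and 2 were at least 1.5-fold lower. Mobp, a myelin structural gene, was 1.41-fold lower. Enpp6, a marker of newly formed oligodendrocytes, went from -2.70 to -3.70. Cryab, a small heat shock gene that also neighbours Il18 on the chromosome, was 2.33-fold lower, and Opalin was 1.40-fold higher. Oligodendrocyte precursor genes had a median of -0.02 at the 29.8 percentile, with Tnr at -0.37. Astrocyte genes had a median of 0.01 at the 7.35 percentile, with Fgfr3 at -0.86, whose probes ranged from -1.52 to -0.20. Microglial genes had a median of -0.04 at the 5.03 percentile, with Selplg at -0.43 and Trem2 at 0.43. Endothelial genes had a median of -0.07 at the 2.64 percentile, with Slco1c1 at -0.38.

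Markers of brain regions were compared because the labels name hippocampus while the extraction protocol and part of the design text speak of prefrontal cortex. Dentate gyrus granule cell genes were higher in Il18-/-, with a median of 0.16 at the 99.9 percentile, 9 of 15 higher and none at 1.5-fold, and with a median of -0.16 when the arrays were scaled to spike-in controls. Lct was 1.33-fold higher and Tdo2, a dentate marker that encodes tryptophan dioxygenase, was 1.29-fold higher. Pyramidal cell genes of fields CA1 to CA3 had a median of 0.04 at the 54.9 percentile, with Iyd at 0.86 and Man1a at -0.71. Neocortical genes had a median of 0.03 at the 66.7 percentile, with Ccn2 at -0.53 and Lmo4 at 0.34. Striatal genes had a median of -0.07 at the 7.66 percentile, with Pde1b at 0.35. Thalamic genes had a median of -0.15 at the 1.30 percentile, with Tnnt1 1.56-fold lower and Cbln1 1.95-fold higher. Hypothalamic peptide genes had a median of 0.04 at the 88.9 percentile, with Tac2 at 2.80 and Avp, the vasopressin gene, at 0.81. These values compare the arrays and do not say which region was sampled.

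Neuronal signalling genes differed by small amounts. GABAergic interneuron genes had a median of -0.11 at the 0.57 percentile, with 17 of 23 lower and Htr3a, a serotonin receptor gene that also lies near Il18, 2.15-fold lower. Glutamatergic synapse genes had a median of -0.08 at the 0.02 percentile, with Grin2a, a glutamate receptor gene, 1.43-fold lower, and the median was 0.00 when each gene was read by its brightest probe. Monoamine and acetylcholine genes had a median of -0.04 at the 36.4 percentile, with Htr2c, a serotonin receptor gene abundant in choroid plexus, 1.83-fold lower. Immediate early genes had a median of 0.00 at the 25.8 percentile, with Fosb at -0.56 and Dusp1 at 0.54. Neurogenesis and proliferation genes were higher in 19 of 22 cases, with a median of 0.11 at the 99.4 percentile and Igfbpl1 1.42-fold higher, and the median was -0.21 under the spike-in scaling.

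Among metabolic and stress genes, the chaperone list had 21 of 25 members lower and a median of -0.10 below every random list, with Sdf2l1 1.48-fold lower and Hspb1 1.44-fold lower. Insulin, growth factor and energy-balance genes had a median of -0.11 at the 0.48 percentile, with Irs2, an insulin receptor substrate gene, 1.33-fold lower. Glucocorticoid-responsive genes had a median of -0.07 at the 0.38 percentile, with Hif3a 1.72-fold lower, and clock genes had a median of -0.11 at the 0.85 percentile, with Per3 1.28-fold lower and Cry1 1.38-fold higher. Sterol synthesis genes had 18 of 21 members lower and a median of -0.08 at the 2.98 percentile, with Sc5d 1.65-fold lower. Oxidative phosphorylation genes were higher in 40 of 43 cases, with a median of 0.09 at the 81.6 percentile, inside the range of random lists, and a median of -0.22 under the spike-in scaling. Reference genes had a median of 0.07 at the 61.6 percentile.

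Neither interferon-responsive nor antigen presentation genes stood apart. Interferon-responsive genes had a median of -0.05 at the 29.3 percentile, with Ifi27 1.38-fold lower and Bst2 1.38-fold lower. Antigen presentation genes had a median of -0.07 at the 8.85 percentile, with Cd74 at -0.27. The H2 genes of that list are close copies of each other, and their single values are uncertain. Blood cell genes had a median of 0.16 at the 99.4 percentile and of -0.16 under the spike-in scaling, with 9 of 12 higher and 3 lower. The neutrophil genes S100a9 and S100a8 were 2.51-fold and 1.95-fold higher, each by 1 probe, S100a8 at dim levels of -4.81 and -3.85. Camp, of the same list, differed by -0.15. Of 32 lists with a percentile, 10 stood apart as lower and 3 as higher. Genes that vary in copy number between strains had a median of 0.08 at the 88.9 percentile. Of the sex-linked genes, Ddx3y differed by 0.60 and Eif2s3y by -0.10.

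**Figure D2:**
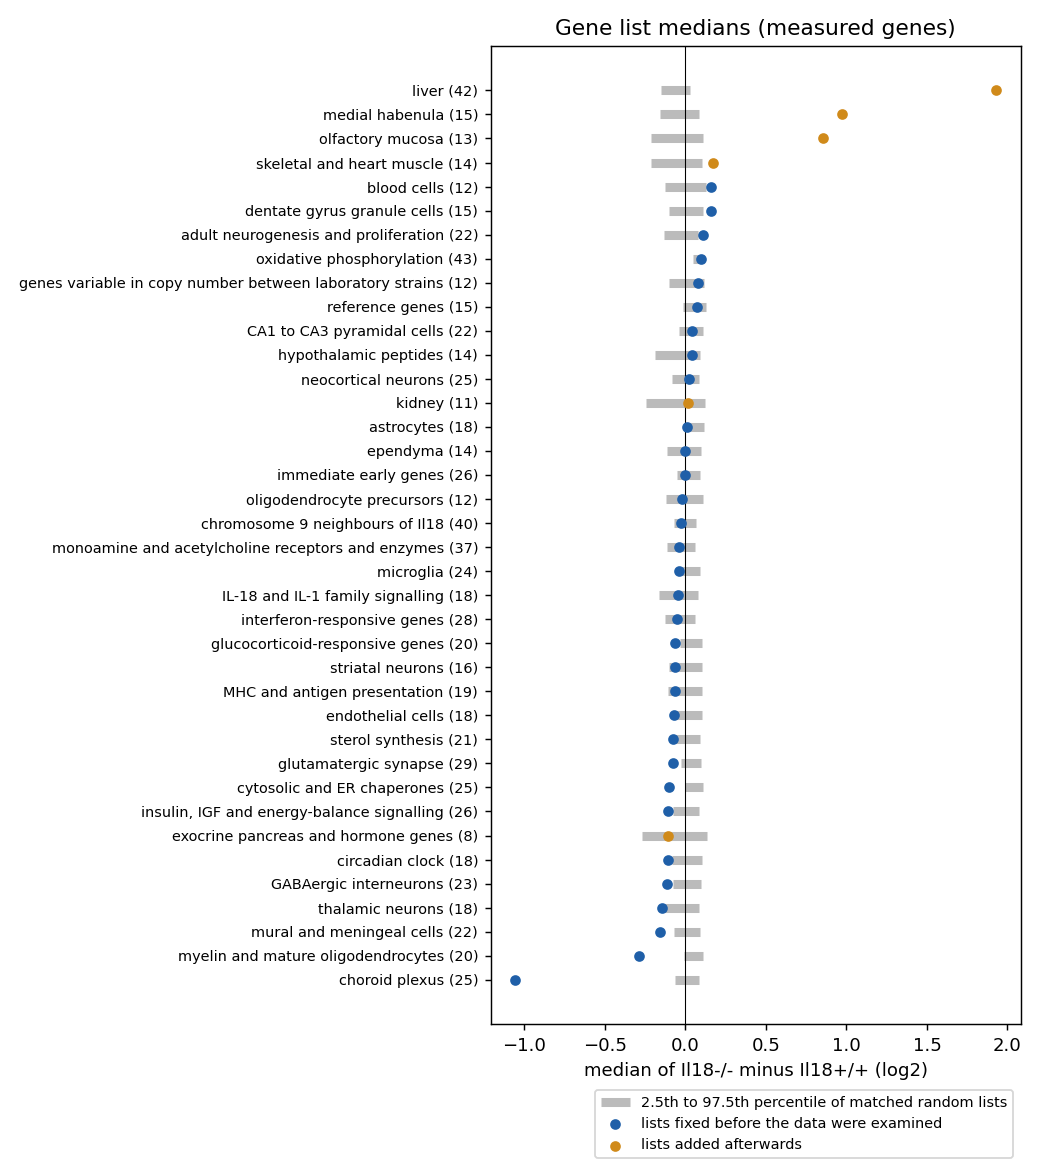
Median difference of each gene list (Il18-/- minus Il18+/+, log2, with the number of measured genes in brackets) and the central 95% of 10000 random lists matched on level as grey bars. Choroid plexus lies lowest at -1.06 and liver highest at 1.93, and the orange lists were chosen after the data were examined.

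Lists for other organs were added after the genes above had been seen, so their values describe a pattern and are no independent evidence. Of 42 measured liver genes 36 were higher in Il18-/-, 29 of them by at least 2-fold, with a median of 1.93 that ranged from 1.02 to 2.01 under the alternatives. Alb, the albumin gene, was 12.5-fold higher, Fgb and Fgg, which encode fibrinogen chains, were 7.95-fold and 7.45-fold higher, and Fga, with dim levels of -5.06 and -5.30, was 1.18-fold lower. A further 8 liver genes were well above background in Il18-/- only, among them Apoa1, at least 3.20-fold higher. All 15 measured genes of the medial habenula, an epithalamic nucleus, were higher, 11 of them by at least 1.5-fold, with a median of 0.97 that ranged from 0.61 to 1.21. Gng8 was 4.59-fold higher, the acetylcholine transport genes Slc5a7 and Slc18a3 were 3.41-fold and 2.98-fold higher, and Pou4f1, a habenular transcription factor gene, was 2.13-fold higher. Of 13 olfactory mucosa genes 11 were higher, 8 of them by at least 1.5-fold, and 2 were lower. Their median was 0.86 and ranged from 0.54 to 0.93. Bpifb6 was 13.3-fold and Omp 1.96-fold higher, while Cnga2 and Gng13 differed by 0.03 and 0.05. Kidney genes had a median of 0.02, a mixed list of exocrine pancreas and hormone genes -0.11 and muscle genes 0.17, the last turning to -0.15 under the spike-in scaling.

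Genes near Il18 on chromosome 9 were compared because a targeted allele carries flanking sequence with it. Among 86 measured genes within 5 Mb, placed by the order of genes in GRCm38.p6, 11 were at least 1.5-fold lower and 5 at least 1.5-fold higher. Bco2, a carotenoid oxygenase gene, was 2.41-fold lower, Cryab was 2.33-fold lower, Htr3a was 2.15-fold lower and Pts, which encodes an enzyme of tetrahydrobiopterin synthesis, was 2.09-fold lower. Chrnb4 was 2.20-fold higher and Apoc3 was 2.54-fold higher, and these also belong to the habenula and liver lists. The median of the 86 genes was 0.03 at the 85.4 percentile, and that of the 40 measured genes in the neighbour list fixed beforehand was -0.03 at the 23.4 percentile. The count of 16 exceeded the highest of 163 windows of as many genes on other chromosomes, which was 12. Of 12 alternatives without the spike-in scaling, which lowers every gene alike, 4 gave a window on another chromosome as many or more. These 4 were the settings on the median signal, which share the same spot values, and the setting with no filter on dim probes. With normexp background correction, 8 genes near Il18 and up to 10 in a window on another chromosome reached 1.5-fold. Fewer genes reached it in all, 113 higher and 107 lower. With no filter both counts were 24. Beyond the 5 Mb limit, 13 of the next 86 measured genes towards lower coordinates reached 1.5-fold and 5 of the next 86 towards higher coordinates. Among the former were Tmem25, the lowest of the named genes, Fxyd2, at 1.73, and Pdzd3, at 1.37, and among the latter was Ppcdc, at -1.78.

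**Figure D3:**
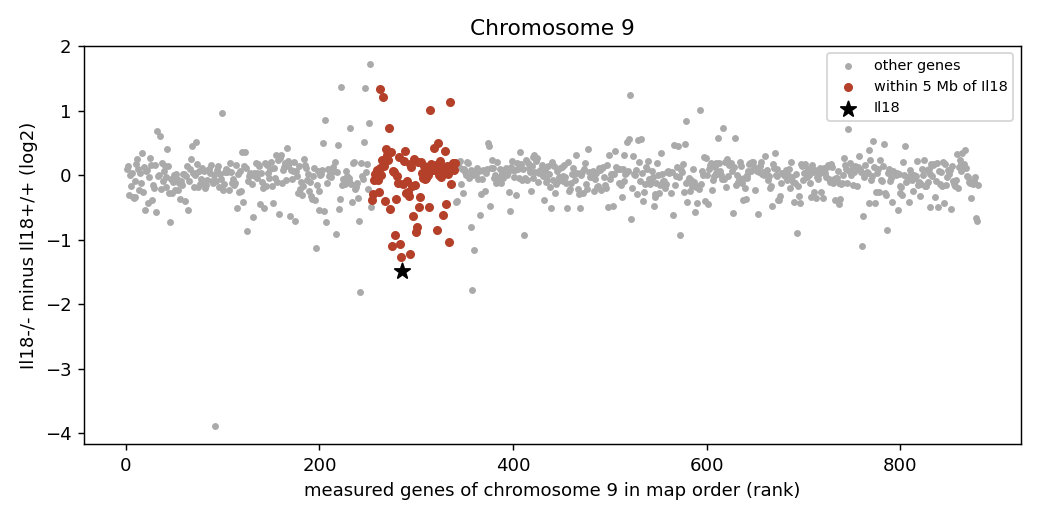
Difference (Il18-/- minus Il18+/+, log2) of the measured genes of chromosome 9 in map order by rank, with genes within 5 Mb of Il18 in red and Il18 as a star at -1.49. Of the 86 genes in red, 16 differ by at least 1.5-fold, 11 lower and 5 higher.

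Some genes were well above background on 1 array only, 216 in Il18-/- and 400 in Il18+/+. For these a lower bound is given, set against the higher of the dim probe's own signal and the lowest signal among probes well above background. In Il18-/- the largest bounds were those of 4930503E24Rik, at least 60.8-fold higher, Vmn1r71, at least 46.0-fold, Olfr1019, at least 16.3-fold, Krt34, at least 13.6-fold, and Olfr301, at least 10.4-fold. In Il18+/+ they were Gm10190, at least 9.28-fold higher, 4930528A17Rik, at least 3.87-fold, Psg-ps1, at least 3.64-fold, Retnlb, at least 3.62-fold, and Vmn1r12, at least 3.59-fold. All of these except Vmn1r12 were read by a spot in a local cluster of spots that differed the same way.

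In all, 451 spots lay in such clusters, 279 higher and 172 lower in Il18-/-, against a median of 71.5 and a highest of 97 after shuffling the positions 100 times. Of 343 spots at least 4-fold higher in Il18-/-, 154 were clustered. Of the 101 genes at least 2-fold higher 23 had a clustered probe, and of the 71 genes at least 2-fold lower 11 had one. In the liver list no member had a clustered probe, and in the choroid plexus list 1 did.

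**Figure D4:**
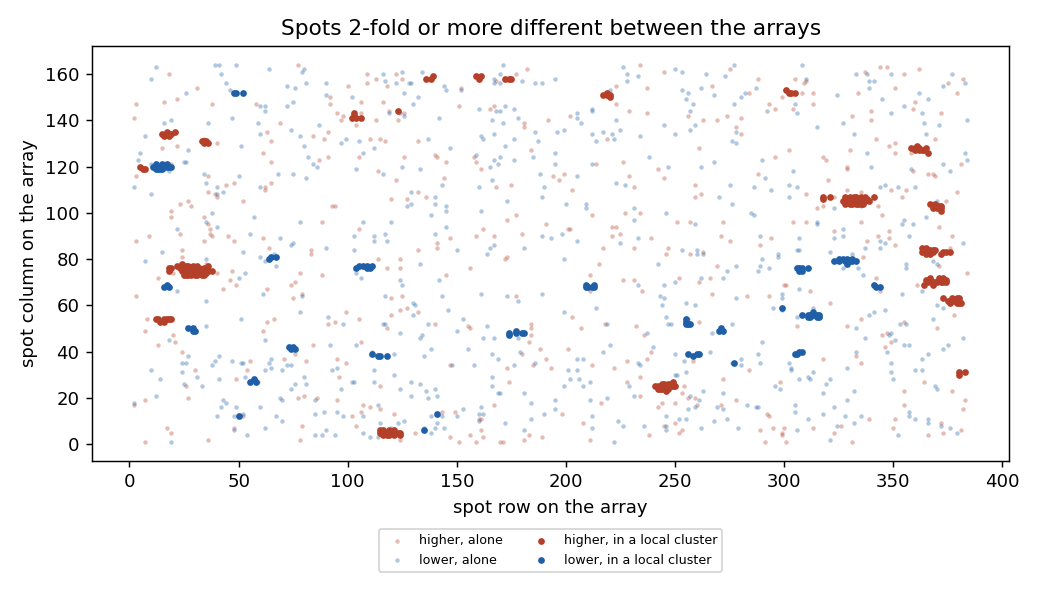
Position by row and column of each spot that differed at least 2-fold between the arrays, red where higher and blue where lower in Il18-/-, with spots in a local cluster drawn larger. Clusters hold 451 spots in all at 1.5-fold or more, of which 279 are higher.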

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

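All tests in this part were chosen after the results they bear on had been seen. Probes with no gene symbol and the spike-in controls gave a signal in data that the comparisons did not use. Of the unnamed probes, 103 were at least 2-fold higher in Il18-/- and 73 at least 2-fold lower, and 40 and 11 of these lay in local clusters of spots. The highest of them, whose target lies on chromosome 18 from 36470130 to 36489110 (mm9), was 43.5-fold higher and was not in a spot cluster. The spike-in control probes, added RNA in fixed amounts, read higher on the Il18-/- array by a median of 0.32 after scaling.

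Choroid plexus genes were lower and medial habenula genes higher in Il18-/-. Spots that differ together with their neighbours on the glass are argued against as the cause, since 1 of the 25 choroid plexus genes and 0 of the 15 measured habenula genes had a clustered probe. Different amounts of adjoining tissue in the dissected pieces and an effect of Il18 loss on these cells cannot be told apart, because there was 1 RNA pool per genotype.

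Liver genes were higher in Il18-/-. Spots that differ together with their neighbours on the glass are argued against as the cause, since 0 of the 42 measured genes had a clustered probe, and a general rise of dim probes by random lists matched on level, the central 95% of whose medians reached up to 0.0283. Liver RNA in the Il18-/- sample may contribute and stays open. Of 41 liver genes dim in Il18+/+, 78.0% were at least 1.5-fold higher, under the 80% set for it. Since 41 of the 42 measured genes counted as dim, this share mostly restates the pattern and cannot decide. An effect of the genotype was not tested.

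Genes near Il18 differed more often than those of windows on other chromosomes in the main scaling. Clustered spots and the genes of the choroid plexus, liver, habenula and olfactory mucosa lists are argued against as the whole cause. Without them 14 genes still differed, against at most 9 in windows on other chromosomes. Flanking sequence of another strain may contribute to the 16 genes, but it stays open. In 4 of 12 alternatives without the spike-in scaling a window on another chromosome had as many or more. Strain variants were not examined, so a count of differing genes cannot by itself identify flanking sequence. Probe mismatch as the whole cause would allow no gene to be higher. Of the 5 higher genes 3 were left without clustered spots and the choroid plexus, liver, habenula and olfactory mucosa genes. As 12 of 166 windows on other chromosomes also reached 3, probe mismatch cannot be told apart from the other explanations.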

How the results depend on the processing

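The median signal alternatives, the spike-in scaling and the removal of clustered spots were chosen after seeing the data. So was the removal of choroid plexus, liver, habenula and olfactory mucosa genes. No paired analysis was possible because each genotype had 1 sample. Il18 lay between -1.81 and -1.28, the choroid plexus median between -1.38 and -0.98 and the number of lists that stood apart between 12 and 15 under all alternatives run. Genes at least 2-fold higher and lower, then 1.5-fold higher and lower, numbered 101, 71, 264 and 405 in the main scaling. They numbered 49, 22, 113 and 107 with normexp, 53, 23, 117 and 106 with normexp and quantile normalization, and 61, 34, 132 and 147 on the median signal without background correction, where Il18 was at -1.28, -1.29 and -1.31 and 8, 8 and 10 neighbours of Il18 reached 1.5-fold. With normexp the choroid plexus median was -0.98. They numbered 395, 500, 815 and 1357 with no filter on dim probes and 8, 19, 31 and 49 among genes above the median level, where 5 of 40 neighbours reached 1.5-fold. Scaling to the spike-ins moved the median of all genes by -0.32 and gave 66, 265, 124 and 1906 genes, Il18 at -1.81, choroid plexus at -1.38 and 26 neighbours. By construction it lowered every list by the same amount. Of the lists that stood apart, the medians of dentate (-0.16), neurogenesis (-0.21), blood cell (-0.16) and muscle (-0.15) genes turned negative, as did every smaller positive median of the lists that had not stood apart. The glutamatergic median turned to 0.00409 with the brightest probe and the muscle median to -0.00344 on the uncorrected median signal. Without the choroid plexus, liver, habenula and olfactory mucosa genes 61 genes were at least 2-fold higher, and without clustered spots 79 were. The share of higher among 1.5-fold genes was 39.5% in the main scaling, 51.4% with normexp, 52.5% with normexp and quantile normalization, 51.7% with loess, 28.6% in the authors' deposited values and 6.11% with spike-ins. The deposited values and the spike-in scaling moved every gene by 1 constant, -0.06 and -0.32, which accounts for their lower shares. For the other settings the cause was not tested. Single genes followed under the alternatives were the named genes and every measured member of the 6 lists chosen after the data were examined. Of their 2904 values, 2053 stayed within the spread of repeated spots (0.07). Settings that only left genes out, or moved every gene by less than this spread, had to give such values. The count therefore does not measure how far single genes depend on the processing. None of the 1154 values of genes at 1.5-fold or more in the main scaling changed sign. Settings that shift all genes alike, by -0.32 at most, could not have turned them. Of the 1750 values of genes with smaller differences, 74 changed sign, 35 of them under the spike-in scaling. Genes not well above background on an array have only a bound there.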

Other observations

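The rule for named genes left out AB124611 for its accession-like name, and it and the genes below were chosen after their values were seen. AB124611, on chromosome 9 but outside the 5 Mb around Il18, was 14.8-fold lower in Il18-/- with levels of 2.56 and -1.33. Scgb1c1, a secretoglobin gene of the olfactory mucosa list, was 33.2-fold higher but lay in a local cluster of spots. Pyy, the peptide YY gene, was 8.58-fold higher and Ins1, an insulin gene, was 2.29-fold lower, while the other measured genes of the list of exocrine pancreas and hormone genes differed by less than Ins1. Nppa, the atrial natriuretic peptide gene, was 2.27-fold higher. Gpr151, a habenular receptor gene, was well above background in Il18-/- only and at least 5.40-fold higher.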
